A study of Gallus gallus with 26 samples.

How the data were processed

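The series holds RNA from chicken ovary in 3 groups: normal ovary (4 samples), early-stage ovarian tumour (4 samples) and late-stage ovarian tumour (5 samples). Each of the 13 sample codes has 2 libraries in the labels, which makes 26 library records. Deposited values cover messenger RNA and microRNA (miRNA, short RNAs that pair with messenger RNAs) for each code. It was therefore assumed that a code has 1 record of each kind. The labels do not say which record is which kind, so columns were matched to groups by their sample code. Nothing in the labels says that the samples of a group came from separate hens, so p-values measure the spread between these samples. The labels' extraction text describes digestion and column binding of nucleic acid and library construction for a BGISEQ-500 sequencer.

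The messenger RNA table deposited by the authors holds estimated counts per gene for 25079 genes. They are not normalized, 30.1% of the values are not whole numbers, and they were rounded before testing. A second table deposited by the authors holds TPM values (scaled for gene length and library total) for the same genes. The miRNA table deposited by the authors holds raw counts for 1235 named miRNAs, of which 458 had no read in any library. A row without a miRNA name held 0 counts and was left out. FastQC, BWA and GATK 3.3.0 are named per the submitters' processing notes, with no role given. The counting program, its treatment of strand and of reads that match several genes, and the genome build are not given in the sources used here. Genes were kept under the symbols of the tables. Of these, 25075 matched the RefSeq table of assembly GRCg7b, which was used for names and kinds of gene alone, and no coordinates are given because the authors' build is not known.

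Total counts ranged from 16273700 to 20118600 per messenger RNA library and from 3038930 to 7728290 per miRNA library. The most abundant gene took between 0.562% and 1.85% of a messenger RNA library, and the most abundant miRNA between 22.5% and 36.3% of a miRNA library. The common coefficient of variation between samples, after counting error, was 33.6% for genes and 40.5% for miRNAs.

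Each kind of RNA was tested with edgeR 4.0.16 in R 4.3.3. All 13 libraries entered one quasi-likelihood fit (glmQLFit with robust estimation) with a mean per group, TMM scaling and the default expression filter (filterByExpr, minimum count 10), which left 16130 genes and 266 miRNAs. The 3 comparisons were early against normal, late against normal and late against early. P-values were adjusted by the Benjamini-Hochberg method over all genes or miRNAs of a comparison, with a threshold of 0.05 and no fold minimum. Values are normalised CPM (the deposited counts divided by the scaled library size) as mean ± SD, and fold changes are on the log2 scale with the standard error (SE) implied by the quasi-likelihood F statistic.

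A total of 28 gene lists and 16 miRNA lists were fixed before the data were examined. The gene lists covered epithelial genes, ovarian carcinoma markers, ovarian cancer drivers, oviduct egg-white secretion, motile cilia, granulosa and theca steroidogenesis, oocyte and germ cell genes, mitosis, DNA replication, T and cytotoxic cells, B and plasma cells, macrophages and myeloid cells, interferon response, fibroblasts and matrix, mesenchymal transition, smooth muscle, endothelium, red blood cells, liver and yolk proteins, intestine, adipose tissue, nerve and neuroendocrine genes, skeletal muscle, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, and stress and immediate early genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison. Each list was tested again with an estimated correlation and with fry. A list score is the mean log2 CPM of its tested genes after each gene was centred on its mean over all 13 libraries.

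The genes named in the text follow a rule set in advance. It took called genes with separate groups and an average log2 CPM of at least 1 (the 8 highest and 8 lowest fold changes per comparison), up to 4 called members per list, and the 2 most abundant members of a list without a called member. For miRNAs it took the called ones (up to 6 in each direction) and the most abundant member of each list. Genes and miRNAs named outside that rule, among them list members that passed only when adjusted over the list alone, were chosen after their values were seen. Some single-gene results are not reported here.

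Before use, the count test and the list test were run on simulated counts with the means, library sizes and dispersions of the real tables. In the simulated late against normal comparison of 15964 genes, 78.9% of genes changed by 2 on the log2 scale and 35.7% of genes changed by 1 were recovered, with 9 false calls. For early against normal (15984 genes) these shares were 79.8% and 26.0%, with 6 false calls, and for late against early (15977 genes) 80.8% and 44.3%, with 7 false calls. For miRNAs, 100.0% of changes of 2 and 36.8% of changes of 1 were recovered in late against normal (263 miRNAs). In early against normal (262 miRNAs) these shares were 70.0% and 20.0%, and in late against early (261 miRNAs) 88.9% and 26.3%. The miRNA tests made 1 false call in late against normal and 0 in the other comparisons. Simulated genes varied independently of each other. The list test recovered 5 of 5 shifted lists and called 0 of 20 unshifted ones in late against normal (16130 genes).

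Alternatives set in advance were DESeq2 1.42.0, other scaling, other filters, fits of only the groups compared, limma voom with quality weights, a minimum absolute log2 fold change of 1, tests on log2(TPM + 1) and log2(TPM + 0.1), a block for shared sample numbers and leaving out each sample in turn. A fit with the first principal component of log2 CPM as a covariate was added after seeing the data. Tests of miRNA seed sites were not run, because no transcript sequences were used here.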

Results

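Messenger RNA and miRNA were profiled in normal chicken ovary (n = 4), early-stage ovarian tumour (n = 4) and late-stage ovarian tumour (n = 5), to compare expression between normal ovary and the tumour stages. Hens develop ovarian tumours spontaneously. Messenger RNA libraries held 16273700 to 20118600 counts and miRNA libraries 3038930 to 7728290. Samples are named by group and the number in their code.

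Ovarian genes were read in all 3 groups. The oocyte and germ cell list was read in tumour libraries too: ZP2, a protein of the egg coat, stood at 341.1 ± 103.1 CPM in normal ovary, 313.9 ± 99.9 in early and 358.9 ± 80.3 in late tumour (SD, n = 4, 4 and 5). CYP19A1, the aromatase that makes oestrogen in the follicle, stood at 236.7 ± 93.4, 301.6 ± 154.0 and 345.6 ± 165.9 CPM, and AMH, a granulosa cell hormone, at 269.5 ± 90.0, 231.5 ± 93.0 and 279.4 ± 29.7 CPM. EPCAM, an epithelial surface protein, stood at 703.4 ± 254.7, 768.3 ± 273.7 and 1088.9 ± 193.2 CPM. Of 19 ovarian carcinoma markers in the table, 15 passed the filter. OVAL, the egg-white protein ovalbumin made by the oviduct, had between 2 and 24 counts in every library.

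The first principal component of log2 CPM held 45.5% of the variance. It averaged 31.1 ± 36.1 in normal samples (from -18.2 to 67.6), 8.09 ± 57.0 in early samples (from -56.7 to 61.7) and -31.3 ± 42.6 in late samples (from -98.2 to 12.4), so groups overlapped on it, and their difference was not tested. The median correlation of log2 CPM between 2 libraries was 0.963 within groups and 0.957 between groups, and for miRNA 0.977 and 0.975. Genes annotated as ribosomal RNA took 4589 ± 756 CPM in normal, 2753 ± 773 in early and 2981 ± 1157 in late libraries. Their ranges overlapped and this difference was not tested. The labels give no batch or day of library preparation, so whether preparation differed between the groups is not known, and every comparison between groups carries that limit.

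Early tumour was compared with normal ovary first. No gene was called by edgeR (0 of 16130), where 813 genes had an unadjusted p under 0.05 and 807 would by chance. DESeq2 called 8 genes and limma voom with quality weights 0. The 2 genes with the smallest p, chosen after their values were seen, were LOC107054136, at 11.04 ± 2.98 CPM in normal and 26.6 ± 3.46 in early samples (log2 fold change 1.26 ± 0.22 SE, adjusted p = 0.463), and LOC107050463, at 42.5 ± 12.98 and 15.6 ± 4.91 CPM (log2 fold change -1.45 ± 0.26 SE, adjusted p = 0.463). Both were among the 8 genes that DESeq2 called (adjusted p = 0.00013 and 0.000373), and voom called neither. Groups did not overlap for 381 genes, or 2.36%, where chance gives 2.86%.

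Among the gene lists, 4 of 28 were called in early against normal, and 0 with an estimated correlation between genes. The smooth muscle list fell (13 of 15 tested members lower, median log2 fold change -1.04, camera adjusted p = 0.000884, and adjusted p = 0.984 with an estimated correlation). ACTG2, smooth muscle actin, stood at 1327 ± 1302 CPM in normal and 236.3 ± 296.7 in early samples, and TAGLN, an actin-binding protein of smooth muscle, at 1364 ± 1299 and 335.8 ± 351.2. The fibroblast and matrix list fell (29 of 35 members lower, median -0.24, adjusted p = 0.00711), as did the T and cytotoxic cell list (15 of 19 lower, median -0.23, adjusted p = 0.00503). Both had adjusted p = 0.984 with an estimated correlation. The mitosis list rose (29 of 36 members higher, median 0.18, adjusted p = 0.00596, and adjusted p = 0.984 with an estimated correlation), with CCNB1, a mitotic cyclin, at 1653 ± 465 and 1698 ± 352 CPM and AURKB, a mitotic kinase, at 425.9 ± 117.3 and 597.7 ± 69.9. No member of any list passed when adjusted over the list alone. Without normal sample 4 the number of called lists was 1, without early sample 11 it was 2, and without early samples 9 or 21 it was 8 or 9. The smooth muscle list was not called without normal sample 4 (camera adjusted p = 0.0763) or early sample 11 (0.154), and the T and cytotoxic cell list without normal sample 7 (0.0662). The fibroblast and matrix list was not called without normal samples 3 (0.178) or 4 (0.0763) or early samples 11 (0.881) or 12 (0.223), nor the mitosis list without normal samples 4 (0.309) or 6 (0.0654) or early samples 11 (0.593) or 12 (0.263). The 24 lists not called had adjusted p from 0.0925 to 0.969, and median, mean and test differed in sign in 6 of them. They included epithelial genes, ovarian cancer drivers, motile cilia, hypoxia and glycolysis, and cholesterol synthesis. BRCA1, a DNA repair gene of the driver list, stood at 155.0 ± 34.4 CPM in normal and 220.9 ± 51.0 in early samples, and CTNNB1, a Wnt pathway gene, at 289.7 ± 72.4 and 262.2 ± 65.4.

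In late tumour against normal ovary, 8 of 28 lists were called, 6 lower and 2 higher, and 0 with an estimated correlation. The smooth muscle list fell, with 15 of 15 members lower and a median log2 fold change of -2.02 (camera adjusted p = 4.12e-07, and adjusted p = 0.726 with an estimated correlation). TAGLN stood at 1364 ± 1299 CPM in normal and 104.5 ± 90.9 in late samples (log2 fold change -3.71 ± 1.00 SE), and ACTG2 at 1327 ± 1302 and 87.4 ± 96.9 (-3.92 ± 1.18 SE). Adjusted over the list alone, 12 of the 15 members passed by edgeR, all lower, against 0 adjusted over all genes. Over all genes DESeq2 called TAGLN (adjusted p = 0.0354) and ACTG2 (0.0398), and voom called TAGLN (0.0453) but not ACTG2. DES, which is in both muscle lists, and ACTA1, muscle filament genes, also passed over the skeletal muscle list alone, DES at 620.2 ± 572.9 and 85.3 ± 81.3 CPM and ACTA1 at 364.8 ± 356.5 and 31.2 ± 21.1 CPM. Over all genes ACTA1, but not DES, was called by DESeq2 (adjusted p = 0.0323), voom (0.0486) and edgeR without normal sample 7 (0.0491). The skeletal muscle list itself was not called (median 0.26, mean -0.72, adjusted p = 0.908). The fibroblast and matrix list fell (32 of 35 members lower, median -0.98, adjusted p = 1.34e-06, and adjusted p = 0.726 with an estimated correlation). COL3A1, a fibrillar collagen, stood at 2798 ± 1603 and 878.8 ± 582.6 CPM, and SPARC, a matrix glycoprotein, at 1128.2 ± 448.8 and 570.3 ± 179.9.

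**Figure D1:**
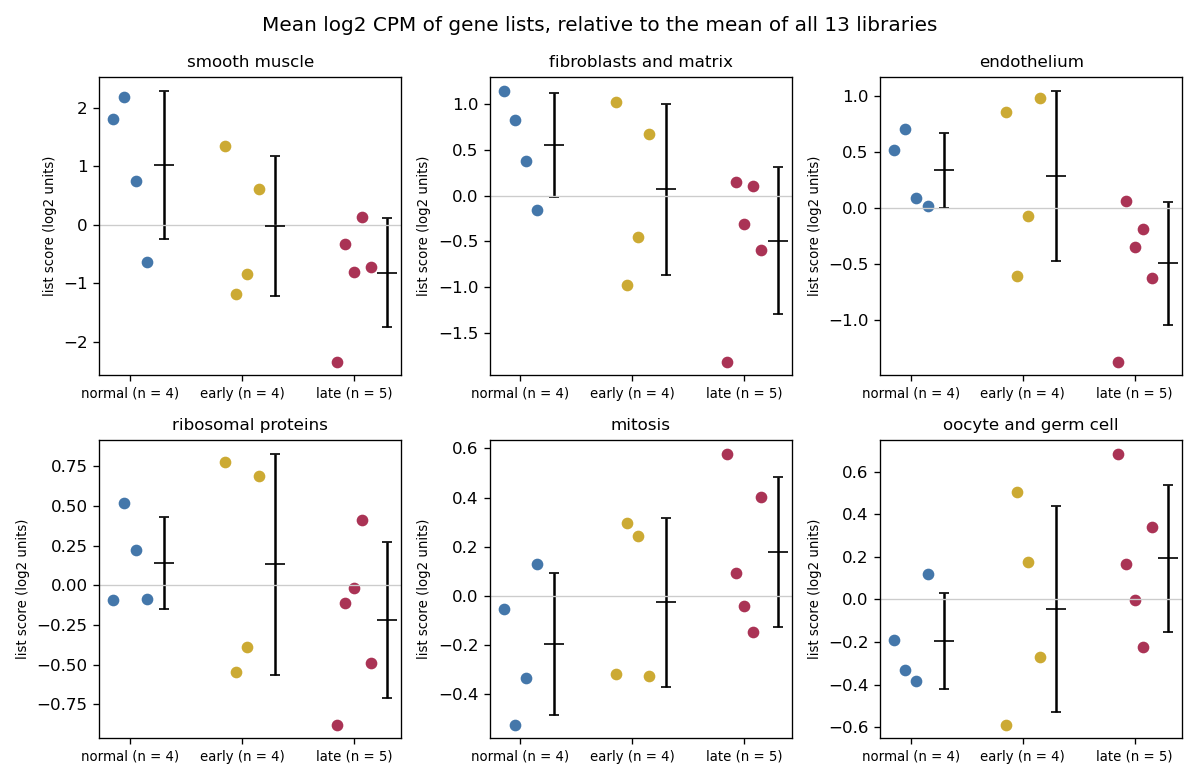
Scores of 6 gene lists in the 13 messenger RNA libraries, by group (normal, early, late), in log2 units relative to the mean of all libraries. Points are libraries and bars the mean ± SD; normal and late libraries overlap in every list shown, and the smooth muscle score averages 1.03 in normal and -0.81 in late samples.

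The endothelium list fell in late tumour (19 of 22 members lower, median -0.74, adjusted p = 5.66e-05, and adjusted p = 0.726 with an estimated correlation), though its most abundant member, EMCN, stood at 223.9 ± 36.2 CPM in normal and 280.1 ± 28.7 in late samples. Over all genes voom called EMCN higher (log2 fold change 0.43, adjusted p = 0.0488), while edgeR and DESeq2 did not call it. Adjusted over the list alone, 4 endothelial genes passed by edgeR, all lower. The macrophage and myeloid list fell (21 of 27 lower, median -0.43, adjusted p = 0.0138), as did the T and cytotoxic cell list (15 of 19 lower, median -0.33, adjusted p = 0.0162) and the ribosomal protein list (47 of 51 lower, median -0.31, adjusted p = 0.000238). With an estimated correlation the adjusted p of these 3 lists was 0.726. Without late sample 3 the macrophage and ribosomal protein lists were not called (camera adjusted p = 0.202 and 0.0636), nor was the T and cytotoxic cell list without normal sample 7 (0.120). CD74, an antigen presentation gene, stood at 655.3 ± 228.7 and 368.9 ± 195.5 CPM, and CSF1R, a macrophage receptor, at 100.3 ± 21.5 and 99.0 ± 21.5. RPS3A, of the small ribosomal subunit, stood at 2450 ± 784 and 2023 ± 831 CPM. The mitosis list rose (33 of 36 higher, median 0.42, adjusted p = 9.8e-07), with CCNB1 at 1653 ± 465 and 2101 ± 451 CPM, and the oocyte and germ cell list rose with 27 of 27 members higher (median 0.45, adjusted p = 0.000238). Both had adjusted p = 0.726 with an estimated correlation. Some members that passed adjusted over the list alone are named after their values were seen. Such passes are not adjusted for the 28 lists tested, and over all genes edgeR called none of these members. FSHR, the follicle-stimulating hormone receptor, passed upwards in the granulosa and theca list (44.6 ± 11.3 and 77.3 ± 14.7 CPM), and ADIPOQ, a fat cell hormone, passed downwards in the adipose list (40.5 ± 27.9 and 6.86 ± 4.12 CPM). ITGA5 and PRRX1 passed downwards in the mesenchymal list, which was not called (adjusted p = 0.121). Median, mean and test had one sign in all 8 called lists and differed in sign in 9 of the others, such as the adipose list. The 20 lists not called had adjusted p from 0.121 to 0.942, and among them were ovarian carcinoma markers, oviduct egg-white secretion, interferon response, liver and yolk proteins, intestine, nerve and neuroendocrine genes, and oxidative phosphorylation. WT1, a transcription factor used as an ovarian carcinoma marker, stood at 321.1 ± 86.0 and 373.0 ± 46.9 CPM, and VIM, a filament of mesenchymal cells, at 1093 ± 92 and 1283 ± 90. IGLL1, of the B and plasma cell list, stood at 3048 ± 2158 and 1254 ± 884 CPM.

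By single gene, edgeR called 0 of 16130 genes in late against normal, with 2893 at an unadjusted p under 0.05 (1211 higher, 1682 lower) where chance gives 807. DESeq2 called 126 genes (27 higher, 99 lower) and voom with quality weights 893 (355 higher, 538 lower). Without normal sample 7 edgeR called 113 genes. LOC107054136, again with the smallest p and named after its values were seen, stood at 11.04 ± 2.98 CPM in normal and 26.8 ± 5.27 in late samples (log2 fold change 1.28 ± 0.21 SE, adjusted p = 0.244). MPC1L, likewise named after its values were seen, stood at 103.0 ± 14.9 and 187.5 ± 24.7 CPM (0.86 ± 0.17 SE, adjusted p = 0.244). DESeq2 called both genes (adjusted p = 0.000123 and 0.00663), as did voom (0.0287 each) and edgeR without normal sample 7 (0.0478 and 0.0491). With all samples, edgeR called neither under other scaling or filters. Groups did not overlap for 421 genes, or 2.61%, where chance gives 1.59%.

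In late against early tumour 10 of 28 lists were called, and 0 with an estimated correlation, where the adjusted p of these lists was 0.722 or 0.726. Endothelium fell (21 of 22 members lower, median -0.87, adjusted p = 3.96e-08), with ribosomal proteins (51 of 51 lower, median -0.42, adjusted p = 7.95e-07), fibroblasts and matrix (31 of 35 lower, median -0.68, adjusted p = 0.000802), smooth muscle (15 of 15 lower, median -0.80, adjusted p = 0.00114), red blood cells (7 of 9 lower, median -1.23, adjusted p = 0.00237) and macrophages and myeloid cells (22 of 27 lower, median -0.42, adjusted p = 0.018). With an estimated correlation the adjusted p was 0.722 for endothelium and red blood cells and 0.726 for the other lists that fell. Mitosis (32 of 36 higher, adjusted p = 0.00101), oocyte and germ cell genes (22 of 27 higher, adjusted p = 0.00889), DNA replication (28 of 35 higher, adjusted p = 0.0124) and stress and immediate early genes (14 of 18 higher, adjusted p = 0.0334) rose, each at adjusted p = 0.726 with an estimated correlation. TYMS, which makes thymidylate for DNA synthesis, stood at 347.4 ± 118.3 CPM in early and 471.5 ± 81.3 in late samples, and HSP90AA1, a stress chaperone, at 1756 ± 242 and 2364 ± 358. The 18 lists not called had adjusted p from 0.0540 to 0.898, and median, mean and test differed in sign in 6 of them. Without early sample 9 or late sample 3 the number of called lists was 3, and without early sample 21 it was 6. Endothelium was called without any single sample. Without early sample 9 all the other lists except red blood cells lost their call (camera adjusted p from 0.0519 to 0.494), and without late sample 3 all except red blood cells and ribosomal proteins did (0.0878 to 0.408). Mitosis, DNA replication, oocyte and macrophage lists lost it without early sample 21 (0.0754 to 0.525), and the last 3 of these without late sample 31 (0.0573 to 0.0789). Red blood cells lost it without early sample 11 (0.204), and stress genes without early sample 12 (0.0795) or late sample 25 (0.190). TF, the egg-white iron carrier ovotransferrin, named after its values were seen, passed downwards adjusted over the list alone (52.9 ± 59.3 and 3.50 ± 3.41 CPM), with 2540 counts in early sample 21. No gene was called by edgeR (0 of 16130, 1023 at an unadjusted p under 0.05); DESeq2 called 9 and voom 0. Groups did not overlap for 256 genes, or 1.59%, where chance gives 1.59%.

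In the miRNA libraries, miR-26a-2-5p was the most abundant, at 27.7% of counts on average, followed by miR-143-3p at 11.8%, miR-99a-5p at 10.5% and miR-451, a red blood cell miRNA, at 8.82% (36.3% in early sample 11). The table also lists miR-26a-5p, a near-identical sequence, and how reads were shared between them is not known. In late against normal, 2 of 266 miRNAs were called by edgeR. miR-223, a miRNA of myeloid blood cells, rose from 355.6 ± 99.8 to 750.8 ± 146.5 CPM (log2 fold change 1.08 ± 0.23 SE, adjusted p = 0.0483), and miR-24-3p fell from 4784 ± 327 to 2425 ± 818 CPM (-0.98 ± 0.21 SE, adjusted p = 0.0483). Neither group overlapped the other for these miRNAs. DESeq2 called 15 and voom with quality weights 0. With library-size scaling neither was called (edgeR adjusted p = 0.142 for each): the log2 fold changes were 1.10 ± 0.29 SE for miR-223 and -0.92 ± 0.27 SE for miR-24-3p, close to those above, and their SE was larger. Over all alternatives the adjusted p ranged from 0.000185 to 0.157 for miR-223 and from 0.00161 to 0.195 for miR-24-3p. Leaving out single samples gave 0 to 10 called miRNAs, with 0 without normal samples 3, 4 or 6 or late samples 3, 23 or 25, 1 without late sample 7 and 10 without normal sample 7. At an unadjusted p under 0.05 there were 49 miRNAs (16 higher, 33 lower), where chance gives 13.3. Groups did not overlap for 16 miRNAs, or 6.02%, where chance gives 1.59%. Adjusted over the list alone, 2 of the 4 members of the miR-143 and miR-145 list passed, both lower, with miR-143-3p at 145240 ± 39604 and 90249 ± 22085 CPM. miR-145-5p, the next most abundant member, did not pass and stood at 12989 ± 2476 and 13962 ± 1669 CPM. Of 6 muscle miRNAs 3 passed, all lower, with miR-133a-3p at 977.6 ± 176.0 and 562.9 ± 333.3 CPM, while miR-1a-3p stood at 222.03 ± 111.2 and 221.96 ± 65.8 CPM. From the miR-17-92 list miR-19b-3p passed upwards over the list alone (3686 ± 479 and 5859 ± 949 CPM), from the miR-199 and miR-214 list miR-214 downwards (667.7 ± 158.1 and 391.3 ± 68.6 CPM), and from the HOX cluster list miR-10b-5p downwards (654.3 ± 229.4 and 309.0 ± 90.9 CPM). Most members of 2 of these lists went the other way: 11 of 17 miR-17-92 members were lower and 6 of 9 HOX cluster members higher. Of the miRNAs named here, miR-145-5p, miR-1a-3p, miR-214 and miR-10b-5p were named after their values were seen.

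**Figure D2:**
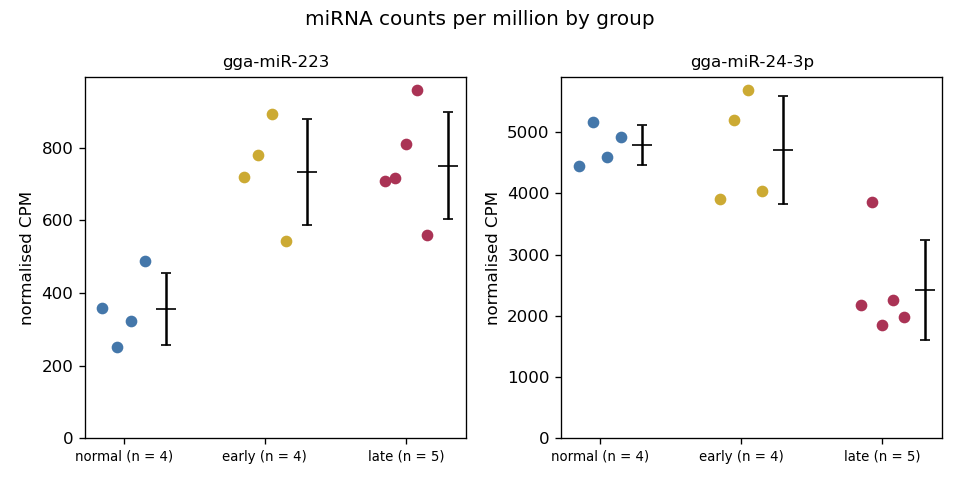
Normalised CPM of miR-223 and miR-24-3p per library, by group (normal, early, late). Points are libraries and bars the mean ± SD; miR-223 averages 355.6 CPM in normal and 750.8 in late samples, and miR-24-3p 4784 and 2425.

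In early against normal no miRNA was called by edgeR (0 of 266, 22 at an unadjusted p under 0.05 and 13.3 by chance), while DESeq2 called 3 and voom 0. Groups did not overlap for 8 miRNAs, or 3.01%, where chance gives 2.86%. miR-223 stood at 733.6 ± 145.9 CPM in early samples (log2 fold change 1.04 ± 0.24 SE, adjusted p = 0.134), and passed adjusted over the list alone. Over all miRNAs miR-223 was called by DESeq2 (adjusted p = 0.00289), and by edgeR without a filter (0.0447) or with a filter of 1 CPM in 4 libraries (0.0485). Without normal sample 7 edgeR called 1 miRNA and without early sample 21 it called 2, miR-223 among them (0.0380 and 0.0376). The other alternatives did not call it. miR-451 stood at 50563 ± 20906 CPM in normal and 165657 ± 201103 in early samples, where early sample 11 had 465195 CPM and the others 32602, 77819 and 87012. Its log2 fold change of 1.71 ± 0.69 SE (adjusted p = 0.547) was 0.39 without that sample. In late against early no miRNA was called by edgeR (0 of 266, 38 at an unadjusted p under 0.05 and 13.3 by chance), and DESeq2 called 4 and voom 0. For 9 miRNAs, or 3.38%, groups did not overlap, where chance gives 1.59%. miR-24-3p stood at 4708 ± 877 CPM in early samples (late against early -0.96 ± 0.21 SE, adjusted p = 0.0633). It was called by DESeq2 (adjusted p = 0.0147), and by edgeR without a filter (0.0206) or with the first principal component as a covariate (0.0475). Leaving out late sample 7 (0.00112) or early sample 21 (0.04999) also gave a call, and the other alternatives did not. Without early sample 21 edgeR called 3 miRNAs, and without early sample 9 or late sample 7 it called 1. The endothelial miR-126-5p, named after its values were seen, was lower in late samples adjusted over the list alone, at 1303.1 ± 311.1 CPM in early and 870.5 ± 169.9 in late. The other and more abundant member of that list, miR-126-3p, did not pass and stood at 49708 ± 5338 and 53130 ± 10452 CPM (log2 fold change 0.10 ± 0.18 SE). Families linked to epithelium and growth control gave no call: miR-429-3p of the miR-200 family stood at 1232 ± 88, 1279 ± 274 and 1117 ± 124 CPM in normal, early and late samples, let-7b at 26524 ± 10197, 21399 ± 5918 and 18768 ± 6376, and miR-21-5p at 34886 ± 5032, 43550 ± 10741 and 34878 ± 6897. The gonadal miR-202-5p stood at 14225 ± 3137, 8815 ± 3023 and 16977 ± 8488 CPM. It was called only in late against early without a filter (log2 fold change 1.03, edgeR adjusted p = 0.0206). The most abundant members of the remaining lists gave no call: miR-182-5p (miR-183 cluster), miR-34a-5p, miR-122-5p (liver) and miR-7b (nerve).

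Fold changes of early and late tumour were both taken against the same 4 normal libraries, which ties them together. Across genes, which are not independent, their Pearson correlation was 0.673 and their covariance 0.150. In simulations of unchanged groups every library, the normals included, was drawn from the normal means. Both simulated comparisons shared the drawn normals, and genes varied independently of each other. These simulations gave a mean correlation of 0.529 and a covariance of 0.0774. With the normal libraries split between the comparisons, in 6 arrangements, the correlation ranged from -0.026 to 0.497 and the covariance from -0.0081 to 0.128. At an unadjusted p under 0.05, 162 genes were higher and 278 lower in both comparisons, where independent lists would share 26.0 and 48.7. The simulated unchanged groups shared 102.9 and 69.6 such genes on average (81 to 133 and 52 to 84 in 20 simulations), and with the normal libraries split 17 to 31 and 18 to 96 genes were shared. Real genes vary together, so the simulated ranges may be too narrow to judge the observed counts. Each split comparison rests on fewer normal libraries and so can find fewer genes. Neither decides whether the shared genes exceed chance.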

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

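The tests of immune miRNAs, of ribosomal RNA genes and of other list scores as covariates were chosen after the result was seen, and the covariate of the first principal component was added after seeing the data. Over 327 groups of samples (list scores, named genes and named miRNAs), 11 had 1 sample far from the rest, or 3.36%, where chance gives about 1 in 20. In normal sample 4 the nerve and neuroendocrine score was 1.31, with the other normals between -0.16 and -0.10. In the same sample PARP12 was at 6.42 and SLC15A1 at 6.32 log2 CPM, with the others from 7.31 to 7.35 and 7.15 to 7.27. In normal sample 3 CSF1R was at 7.05, above 6.46 to 6.54. In early sample 11 LOC107054136 was at 4.99, above 4.62 to 4.66, and in early sample 9 miR-429-3p was at 10.7, above 10.1 to 10.2. In late sample 3 EPCAM was at 10.5, above 9.90 to 10.1, and let-7b at 12.9, below 14.3 to 14.5. In late sample 7 miR-24-3p was at 11.9, above 10.9 to 11.1. The ovarian carcinoma marker score was -0.22 in late sample 31, below 0.16 to 0.26, and the stress score 0.23 in late sample 25, above -0.05 to 0.02.

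The shift of gene lists between late tumour and normal ovary was set against chance, sequencing depth and the make-up of the tissue piece, and chance could not be excluded: 46 of 100 splits of these 9 samples called at least 8 lists, and another split called 15. All 8 lists kept their call and direction after every library was thinned to the lowest total. Totals ranged only from 16273700 to 20118600 and log2 CPM is already scaled for depth, so this check could change little. It showed no effect of depth within that range and decides no more. With the smooth muscle score as a covariate, which itself differed by -1.84 ± 0.75 SE, 0 of the other 7 lists kept its call, and the fibroblast and matrix score difference went from -1.04 ± 0.53 SE to 0.16 ± 0.25 SE. A differing amount of muscle and matrix in the pieces is therefore a candidate explanation, but not one set apart from others that go with it: the scores of the 27 other lists, used in the same way, left 0 to 8 calls (median 5), with 0 for endothelium and 1 for mitosis. The direction turned in 5 lists, ribosomal proteins (camera adjusted p = 2.47e-09) and macrophages (0.0427) being called the opposite way and DNA replication (0.0160), B and plasma cells (0.0418), interferon response (0.0427) and oxidative phosphorylation (0.0418) newly called, none of them with an estimated correlation (adjusted p = 0.872), and tumour stage stays open and untested, since a tumour may itself replace muscle and matrix.

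miR-223 was higher in all 9 tumour samples than in any normal sample. Without the 10 most abundant miRNAs its log2 fold change in late against normal was 1.14 ± 0.21 SE (edgeR adjusted p = 0.0237). The main fit was already TMM-scaled, which adjusts for a few miRNAs taking most of the counts, so this refit cannot decide on that cause. With library-size scaling, which does not adjust for it, the log2 fold change was 1.10 ± 0.29 SE, so scaling changed the estimate little. More white blood cells in the tumour pieces could not be told apart from a change within cells: the other 8 immune miRNAs were all higher, with a median log2 fold change of 0.31, while the macrophage and myeloid gene list was lower. That list was not called with an estimated correlation (camera adjusted p = 0.726) or without late sample 3 (0.202). A change with the tumour itself was not tested.

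LOC121107023, annotated as a ribosomal RNA gene, had 7519, 4217, 3055 and 778 counts in the normal samples, 870 in late sample 25 and 0 in the other 8 tumour samples, where 0 allows up to 3 counts. It was not called by edgeR (adjusted p = 0.916 in early against normal and 0.249 in late against normal). Whether more ribosomal RNA left in the normal libraries is the cause stays open. Late sample 25 had the most ribosomal RNA of the tumour samples, at 4635 CPM, and normal sample 7 the least of the normals, at 3559. Against this, early sample 21 had 3719 CPM, above normal sample 7, and 0 counts of LOC121107023. The other 30 tested ribosomal RNA genes had a median log2 fold change of -0.68 in early against normal, and the lowest was -1.96. The median was also -0.68 over the 19 distinct sets of counts among them, since some copies hold identical counts. A general difference of that size does not by itself give 0 counts in every early sample, but it may be part of the cause. Of 28 genes at 5 CPM or more in some samples and at most 1 count in others, 85.7% had LOC names, against 19.9% of tested genes. Such genes followed a group boundary 2 times. In 1000 regroupings the mean was 0.281 and the central range reached 4. Several such genes had the same count in every library and so count together in a regrouping, which widens that range. The test therefore cannot decide whether differences between individual samples account for them. Reads moving between near-identical gene copies were not tested.

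Other splits of the samples were counted for each comparison. For messenger RNA the real splits called 0 genes, a count that every split reaches (35 of 35 for early and normal samples, 100 of 100 for late and normal and 100 of 100 for late and early), so this count tests nothing. The highest other splits, picked as the highest, called 762, 2630 and 2830 genes. Each set the 4 samples at one end of the first principal component against the rest. The first and the third had samples of both groups equally on that side (normal samples 3 and 4 with early samples 9 and 21, and early samples 11 and 12 with late samples 3 and 31), which points to a structure other than the groups that was not tested further. The second was the real grouping with normal sample 7 and late sample 25 exchanged, so it largely followed the groups. At an unadjusted p under 0.05 the real counts of 813, 2893 and 1023 genes were reached by 12 of 35, 5 of 100 and 28 of 100 splits, with 4406, 5544 and 5782 in the highest others. The 4 lists called in early against normal were reached by 30 of 35 splits (highest other 14) and the 10 in late against early by 39 of 100 (highest other 15). Chance is not excluded for these counts at an unadjusted p or for these lists. For miRNA, 3 of 100 splits of late and normal samples gave 2 or more calls (highest other 5), under the 5% set in advance. This was 1 of 7 counts that could be tested, and the count of 2 was 0 with library-size scaling, fits of 2 groups, voom and the covariate, and without each of 6 of the 9 samples in turn, so chance is excluded for it only by that rule and not firmly. In early against normal and late against early the real count of 0 miRNAs is again reached by every split (35 of 35 and 100 of 100) and tests nothing, with 3 and 1 in the highest others.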

How the results depend on the processing

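All settings were chosen before the data were examined except the first principal component as a covariate, added after seeing the data. By edgeR 0 genes were called in each messenger RNA comparison under other scaling, filters, fits of 2 groups and a fold minimum. DESeq2 called 8, 126 and 9 genes in early against normal, late against normal and late against early. Voom called 893 in late against normal. With TPM, 1 gene was called in early against normal at a pseudocount of 0.1 and 1 without a filter, 1 in late against normal without a filter and 1 in late against early at 0.1. The covariate gave 1 gene in late against normal. Leaving out single samples gave 0 to 113 genes in late against normal and 0 in the others.

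For miRNA, DESeq2 called 3, 15 and 4 in the same order, and no filter 6, 6 and 5. A filter of 1 CPM in at least 4 libraries, looser than the main filter for miRNAs (301 against 266 tested), called 1 in early against normal and 1 in late against normal. In late against normal RLE scaling gave 1, library size only 0, fits of 2 groups 0, voom 0, the fold minimum 1 and the covariate 0, and the covariate gave 2 in late against early. Leaving out single samples gave 0 to 2, 0 to 10 and 0 to 3 miRNAs. Sample numbers 3 and 7 occur in normal and late samples, and with this replicate block 0 genes and 1 miRNA were called. The deviations of same-numbered samples correlated at 0.0021 and -0.14. With no differently numbered samples set beside them, these values cannot decide whether the numbers mark pairs.

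Of gene lists, 0 were called with an estimated correlation and 0 with fry in each comparison. The covariate gave 5, 1 and 6 lists in the same order, of which 2, 0 and 3 were called the same way without it. This component averaged 31.1 in normal and -31.3 in late samples, so the covariate also takes up part of that difference, and genes at an unadjusted p under 0.05 went from 2893 to 1074 in late against normal. Single samples left out gave 1 to 9, 6 to 11 and 3 to 12 lists. List directions turned under the covariate in late against normal for oocyte and germ cell genes (adjusted p = 0.431), mitosis (0.874), macrophages (0.130), fibroblasts and matrix (0.896) and ribosomal proteins (5.01e-11). In late against early they turned for oocyte and germ cell genes (0.348), mitosis (0.486), DNA replication (0.919), macrophages (0.191), interferon response (0.00995), fibroblasts and matrix (0.351), mesenchymal transition (0.0296), smooth muscle (0.555) and ribosomal proteins (0.191). Ribosomal proteins turned in early against normal without early samples 9 (0.0123) and 21 (0.0258), and leaving out single samples gave 0.0114 to 0.849. The cause was not tested for any of these. The overlap of genes called by edgeR in both tumour comparisons against normal tests nothing: it was 0 in the main fit and with the normals split, because at least 1 of the lists was empty. In 4 of 6 splits both lists were empty. Early tumour against normal samples 3 and 4 called 10 genes, and late tumour against the same samples called 665. DESeq2 called LOC107054136 higher (adjusted p = 0.00013 and 0.000123) and LOC107050463 lower (0.000373 and 0.00663) in both comparisons. These share their normal libraries, and the full DESeq2 overlap was not counted. Seed-site tests were not run. Depth limits the rarer miRNAs, at 3038930 counts in the smallest miRNA library.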

Other observations

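The tests of the 5 pairs were chosen before their results were seen, and the bound used to weigh the negative ones after. Across the 13 samples the smooth muscle gene score and miR-143-3p, a miRNA of smooth muscle, which were read in separate libraries, had a Pearson r of 0.857 (permutation p = 0.00016, adjusted 0.0008 over 5 pairs) and a Spearman rho of 0.830 (permutation p = 0.00078, adjusted 0.0039). Without normal samples 3 and 4, the farthest from the median, r was 0.8291, and after removal of group means it was 0.792. The test, set before its result was seen, is consistent with both following the same cells. miR-145-5p of the same miRNA list, added after its values were seen, had r = -0.178 (permutation p = 0.557, adjusted 0.602 over 6 relations) and rho = 0.0714 (permutation p = 0.820, adjusted 0.820), with r = -0.0772 without the 2 farthest samples. Its upper 95% bound of 0.413 lies below the r of miR-143-3p, so the relation was not seen for this member and a shared source stays a hypothesis for miR-143-3p alone.

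For the other 4 pairs, also set in advance, no relation passed. The red blood cell list and miR-451 had r = 0.277 (permutation p = 0.372, adjusted 0.465) and rho = 0.159 (permutation p = 0.602, adjusted 0.656), with r = 0.567 without the 2 farthest samples. T and cytotoxic cells and miR-142-3p had r = 0.310 (permutation p = 0.303, adjusted 0.465) and rho = 0.418 (permutation p = 0.157, adjusted 0.371), with r = 0.405 without 2 samples. Endothelium and miR-126-3p had r = 0.161 (permutation p = 0.602, adjusted 0.602) and rho = 0.137 (permutation p = 0.656, adjusted 0.656), with r = -0.278 without 2 samples. The macrophage and myeloid list and miR-223 had r = -0.341 (permutation p = 0.253, adjusted 0.465) and rho = -0.363 (permutation p = 0.223, adjusted 0.371), with r = -0.259 without 2 samples. Its upper 95% bound of 0.258 leaves little room for miR-223 to rise with this score in these samples. The score itself went with the smooth muscle score within groups (r = 0.847). The pair therefore cannot decide whether miR-223 came from myeloid cells. The use of that bound was decided after the r values were seen. The rule set in advance, r under 0.3, counted the macrophage pair against a shared source. It would also have counted the red blood cell and endothelium pairs so, but their intervals reach 0.718 and 0.654. These stay open too.

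Normal sample 4 stood apart in neuroendocrine RNAs, which were chosen after their values were seen. CHGA, a protein of hormone granules, was at 368.5 CPM there and between 24.2 and 74.8 in the other 12 libraries, and CHGB at 222.8 against 28.7 to 62.0. In its miRNA library gga-miR-375, a miRNA of endocrine cells, was at 2270.9 CPM against 0.792 to 194.5 elsewhere, and gga-miR-7 at 709.1 against 9.80 to 131.9.

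LYZ, the egg-white and phagocyte lysozyme, had 644 counts in late sample 23 and between 1 and 16 in the other 12 libraries. The genes in this paragraph were chosen after their values were seen. PAX2 had 19 counts in normal sample 4 and at most 2 elsewhere, and OVALY had 38 in the same sample and at most 9 elsewhere.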
